A study of Mus musculus with 31 samples.

How the data were processed

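The series measured messenger RNA in the left liver lobe of female mice of 4 inbred strains, MA/MyJ, NZW/LacJ, SM/J and WSB/EiJ, given PF-04287881, a candidate antibiotic, or sterile water. Per the labels, the dose was 600 mg/kg by gavage once daily for 7 days and tissue was taken 24 hours after the last dose. The 31 arrays formed 8 groups of strain and treatment with 4 animals each, except 3 treated WSB/EiJ animals, since 1 animal of that group died of a gavage error. Per the labels' protocols, total RNA was isolated on columns, amplified in 1 round, labelled with biotin and hybridised to 1-colour Affymetrix arrays.

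The deposited values were in log2 units per probe set. Per the labels, the authors made them with Affymetrix Power Tools and the RMA method, which corrects background, normalises the arrays by quantiles and summarises each probe set. The version of either tool, the detection calls and the scan dates were not given in the sources used here, and no genome build was named, so no coordinates are given. The values ran from 2.71 to 14.9, and the medians of the 31 arrays lay between 6.43 and 6.54.

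Of 44721 probe sets, 34728 carried 1 gene symbol, 872 carried several and 9121 carried none, the 60 control probe sets among them. Symbols were brought up to date through Entrez gene numbers in a table of the GRCm38.p6 annotation, used for names alone, which held the genes of 34525 probe sets. Each gene was represented by its probe set with the highest mean over all arrays, a choice that applied to 7531 tested genes with several probe sets. Genes were kept when their value exceeded the median of all probe-set values, 6.49 in log2 units, in at least 3 arrays. This left 12890 of 18147 genes for testing and set 5257 dim genes aside.

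A linear model with 1 mean per group was fitted to all 31 arrays with limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, for reading. The spread of each gene was moderated by eBayes with 3.17 prior and 23 residual degrees of freedom. The comparisons were PF-04287881 minus vehicle in each strain, the mean of these 4 differences, a moderated F test of the 3 strain-by-treatment terms, and interaction contrasts that follow the coding of the series. One contrast set the mean effect in MA/MyJ and NZW/LacJ, coded for Kupffer cell vacuolation, against that in SM/J and WSB/EiJ. The other set the effect in NZW/LacJ, coded for single cell necrosis, against the mean of the other strains, and both were repeated on vehicle levels. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, tests being two-sided. Errors given with ± are the model's standard errors of a log2 difference. The p-values measure the spread of animals within these strains, not the spread between strains. The number of arrays limits the precision of every value.

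Gene lists were fixed for this tissue and treatment: 28 pathway lists and 12 lists of cell type markers. Lists with at least 5 tested members, 39 of the 40, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with the correlation estimated for each list. Member counts are given over all genes tested and adjusted over the list alone. Per animal, a list's score was the mean over its members of the log2 value minus the mean of the strain's vehicle animals.

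Genes were named by a rule fixed, like the lists, the comparisons and most alternatives, before the data were examined. It took genes with 1 symbol, and predicted or clone names (Gm, Rik, LOC, BC and AI symbols, 668 of the tested genes) were counted and not named. For the average effect it took the 12 largest changes in each direction past the threshold with the same sign in all 4 strains. For each strain it took the 5 largest in each direction. For the vacuolation contrast it took the 10 largest in each direction where the effects of both coded strains lay on the same side of both others, and for the necrosis contrast the 10 largest in each direction where the NZW/LacJ effect lay beyond all 3 others. For vehicle levels it took the 6 largest in each direction with strain means separated in the same way, and for each list the 4 largest members that passed, or the 2 largest as values where none did. Members named beside a count of 5 or fewer that are not among these 4 were chosen after their values were seen.

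The procedure was tested on simulated data with 12890 genes, 100 of them changed by 0.5 in log2 units and another 100 by 1. At a log2 change of 1, the average effect recovered 100 of 100 genes, the single strains 94 to 97, the F test 85, the vacuolation contrast 95 and the necrosis contrast 92. At a change of 0.5 these were 96, 67 to 80, 45, 68 and 59, so smaller changes were missed more often. False calls made up 1.78% to 6.77% of the genes called. With no change, 0 or 1 genes were called in any comparison. The simulated noise was independent between genes, with 1 spread per gene for all groups, estimated without the array labelled WSB/EiJ PF-04287881 animal 3. It held no correlation between genes and no strain of wider spread, so these shares need not hold for the real arrays.

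The identity of each array was checked on probe sets private to each strain (for the array in doubt, 30 of WSB/EiJ and 10 of NZW/LacJ) and on 300 genes that separate treated from vehicle NZW/LacJ animals. Because 1 array failed this check, every count was computed again without it, an alternative chosen after seeing the data where it was combined with another setting. The other alternatives were 2 further normalisations, no filter or a stricter filter at the percentile 75, the mean of all probe sets of a gene, eBayes with trend and robust options, array weights, the animal number as a block, a fold minimum of 1.5, the arrays of a strain alone, and each animal or each strain left out. The set test of each list without each animal was added after the results were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probe sets without 1 gene name were left out of the gene comparisons because no gene could be assigned, and the scanner's raw files were not used here.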

Results

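Liver RNA was measured on 31 arrays from 4 inbred mouse strains. MA/MyJ, NZW/LacJ and SM/J each gave 4 arrays after 7 daily doses of PF-04287881 and 4 after vehicle, and WSB/EiJ gave 3 and 4. In the coding of the series, the livers of MA/MyJ and NZW/LacJ showed vacuolation of Kupffer cells, the resident macrophages, and those of NZW/LacJ also showed single cell necrosis. The strain comparisons therefore ask which transcripts respond to the drug in every strain and which follow these microscopic findings. Changes are log2 differences, PF-04287881 minus vehicle, ± 1 standard error, and gene tests covered 12890 genes.

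Probe sets private to a strain placed 30 of the 31 arrays with the strain of their label. The array labelled WSB/EiJ PF-04287881 animal 3 lay at 0.000305 on a scale where the other strains average 0 and WSB/EiJ 1, while the other WSB/EiJ arrays lay between 0.970 and 1.05 except vehicle animal 4, at 0.777. On the corresponding NZW/LacJ scale it lay at 1.03, against 0.965 to 1.03 for the arrays labelled NZW/LacJ. On 300 genes that separate treated (1) from vehicle (0) NZW/LacJ animals it lay at 0.0266, within the vehicle range of -0.0411 to 0.0339. The gene count of every comparison is therefore also given without this array, which leaves 2 treated WSB/EiJ animals. WSB/EiJ vehicle animal 4 also lay apart on the first principal component, at 13.2 against 31.4 to 60.2 for the other WSB/EiJ arrays outside the array in doubt. On probe sets private to MA/MyJ, NZW/LacJ and SM/J it lay at 0.00463, -0.0120 and -0.0325, so it resembled none of these strains, and the cause was not tested.

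**Figure D1:**
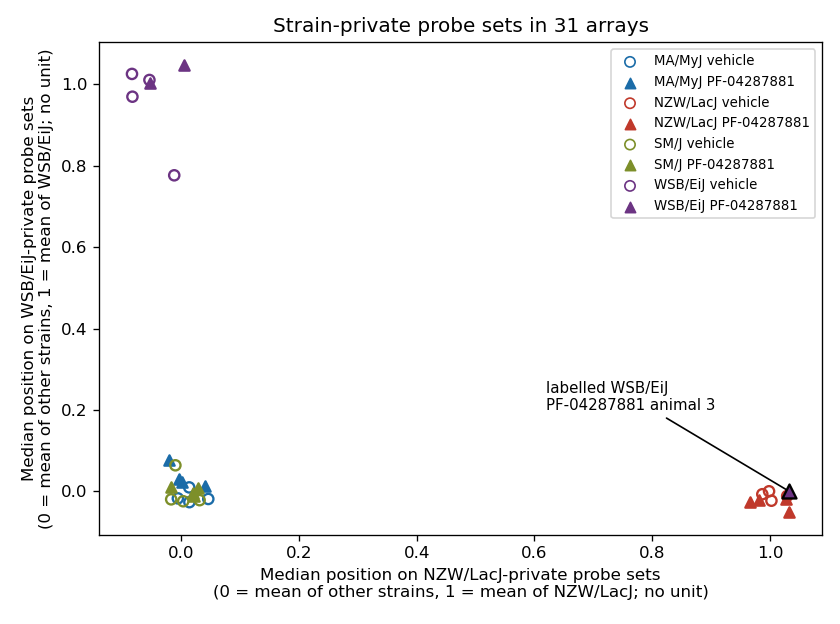
Median position of each of the 31 arrays on probe sets private to NZW/LacJ (x axis) and to WSB/EiJ (y axis), both without unit and scaled so that 0 is the mean of the other strains and 1 the mean of the named strain. Open circles are vehicle arrays and triangles PF-04287881 arrays; the array labelled WSB/EiJ PF-04287881 animal 3, outlined in black, lies at 1.03 and 0.000305, among the NZW/LacJ arrays.

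The average effect over the 4 strains asks what the drug did to the liver when every strain counts alike, and can rest on some of them. The largest rises with the same sign in every strain were those of macrophage genes. Cd68, a lysosomal membrane glycoprotein of macrophages, rose by 1.99 ± 0.21 (adjusted p = 2.05e-07, 15 treated and 16 vehicle arrays), with 2.57 in MA/MyJ, 1.66 in NZW/LacJ, 1.61 in SM/J and 2.12 in WSB/EiJ. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 1.96 ± 0.26, and Lgals3, a galectin abundant in macrophages, by 1.91 ± 0.20. Among the largest falls were those of the elongase Elovl3 at -1.54 ± 0.25 (adjusted p = 5.57e-05) and the acyl-CoA thioesterase Acot2 at -1.22 ± 0.16.

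Other large rises with the same sign in every strain were those of Ifi27l2b, an interferon-inducible gene (1.80 ± 0.11, adjusted p = 8.12e-11), and of Uap1l1 (1.75 ± 0.13). Anxa5, which encodes a phospholipid-binding annexin, rose by 1.73 ± 0.12 (adjusted p = 1.45e-10). The sterol synthesis enzymes Cyp51 and Nsdhl rose by 1.55 ± 0.30 and 1.53 ± 0.23. Lysozyme Lyz1 rose by 1.49 ± 0.19, the fatty acid-binding protein Fabp5 by 1.47 ± 0.22, the macrophage elastase Mmp12 by 1.46 ± 0.24 and the adhesion molecule Vcam1 by 1.45 ± 0.20. The average of Mmp12 rested on MA/MyJ (3.34) and NZW/LacJ (1.68), with SM/J at 0.30 (adjusted p = 0.84) and WSB/EiJ at 0.51 (adjusted p = 0.52). Without the array labelled WSB/EiJ PF-04287881 animal 3, Mmp12 was at 0.91 in WSB/EiJ (adjusted p = 0.22). Among the falls were the antimicrobial peptide gene Leap2 (-1.28 ± 0.37, adjusted p = 0.0142), the manganese transporter Slc30a10 (-1.15 ± 0.10, adjusted p = 2.09e-08) and the hepatokine Fgf21 (-1.15 ± 0.26). So were the thioesterase Acot1 (-1.06 ± 0.17) and the clock activator Arntl (-1.04 ± 0.15). The average of Arntl rested on NZW/LacJ (-2.83) and SM/J (-1.08), with MA/MyJ at -0.15 and WSB/EiJ at -0.09, or at 0.33 without the array labelled WSB/EiJ PF-04287881 animal 3. The glycogen-targeting subunit Ppp1r3c (-1.01 ± 0.21), the aldo-keto reductase Akr1c19 (-1.0 ± 0.18), the retinol saturase Retsat (-0.93 ± 0.19), the lipoprotein lipase regulator Angptl8 (-0.90 ± 0.23) and the carboxylesterase Ces1e (-0.90 ± 0.13) also fell. Over all arrays, Cyp51 (3.11), Fgf21 (-2.39) and Retsat (-1.25) passed in WSB/EiJ alone among the single strains. Elovl3 passed in NZW/LacJ alone (-2.79), and Leap2 and Angptl8 in no single strain. Some of these patterns depended on the array labelled WSB/EiJ PF-04287881 animal 3. Without it Retsat passed in all 4 strains (-1.02, -0.72, -0.72 and -2.22 in MA/MyJ, NZW/LacJ, SM/J and WSB/EiJ). Elovl3 (-1.94) and Leap2 (-2.50) then also passed in WSB/EiJ, while Cyp51 and Fgf21 still passed there alone.

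**Figure D2:**
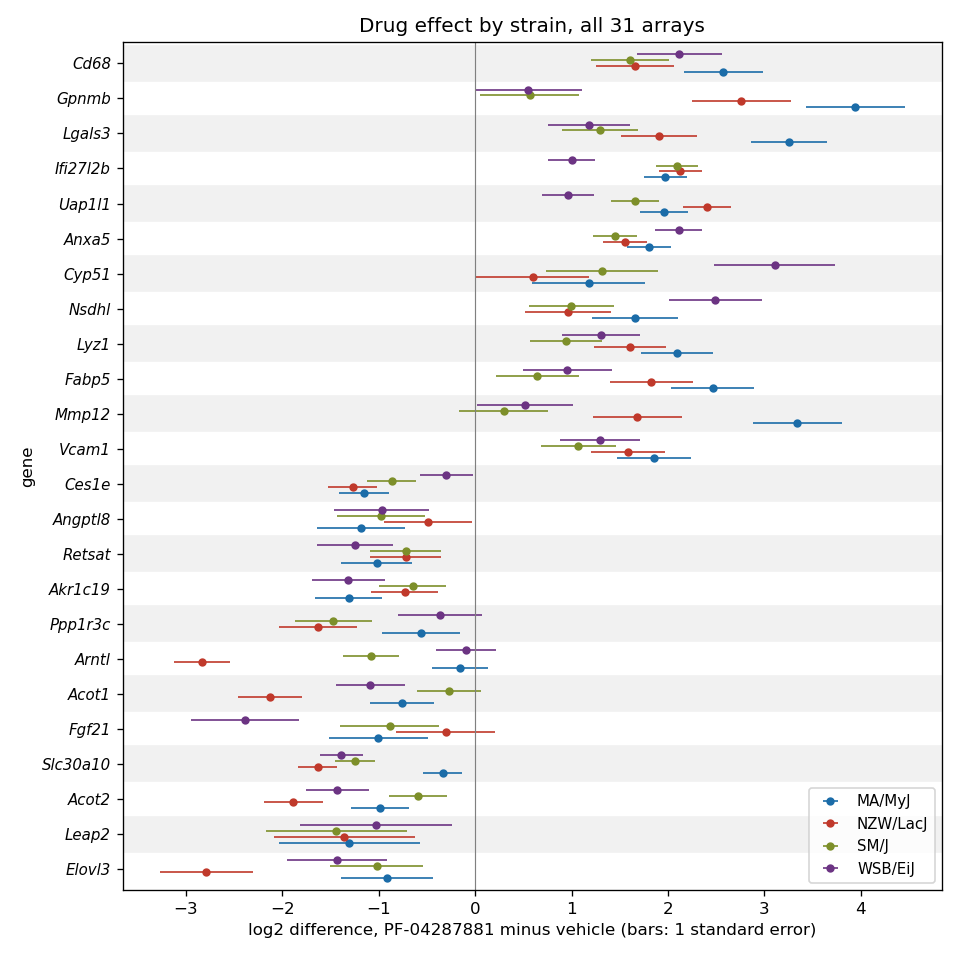
Log2 difference, PF-04287881 minus vehicle, of the 24 genes named for the average effect, with 1 point per strain and bars of ± 1 standard error, from all 31 arrays. Every gene has the same sign in the 4 strains, which for Arntl in WSB/EiJ does not hold without the array labelled WSB/EiJ PF-04287881 animal 3 (0.33). Gpnmb ranges from 0.55 in WSB/EiJ, or 1.15 without that array, to 3.94 in MA/MyJ.

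In all, 2859 genes passed, 1709 higher and 1150 lower. Of these, 1732 (60.6%) had the same sign in all 4 strains, which the selection itself favours. Without the array labelled WSB/EiJ PF-04287881 animal 3, 4209 genes passed, 2376 higher and 1833 lower, of which 2743 were shared with the count over all arrays.

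Of the 39 lists tested, 12 were called higher and 7 lower in the average effect, and 20 were called without the array labelled WSB/EiJ PF-04287881 animal 3, 18 of them in both. With an estimated correlation 1 of the 19 calls held, and 0 lists were called when that array was also left out. Lysosomal enzymes and membrane proteins had 51 tested members, of which 38 rose and 3 fell, against 38 and 4 adjusted over the list alone and 38 and 4 without that array. Cd68 (1.99), the protease Ctss (1.09), the hexosaminidase Hexa (0.85) and the sulfatase Arsa (0.80) rose most, and Ctsc (-0.32), Ids (-0.19) and Acp2 (-0.22) fell. The set test gave adjusted p = 5.79e-16, and adjusted p = 0.0876 with an estimated correlation. Of 16 subunits of the vacuolar proton ATPase, the pump that acidifies lysosomes, 11 rose and none fell (12 adjusted over the list alone, 14 without that array). Among them were Atp6v0b (0.45), Atp6v1e1 (0.35), Atp6v0d2 (0.35) and Atp6v1d (0.32). Its adjusted p was 1.12e-06, with adjusted p = 0.322 with an estimated correlation. Of 27 genes of phospholipid breakdown and lipid-loaded lysosomes, 13 rose (15 adjusted over the list alone, 15 without that array). Among them were Gpnmb (1.96), the lipoprotein-associated phospholipase Pla2g7 (1.05), Lpl (0.61) and Lss (0.53), the last lost without WSB/EiJ treated animal 1 (0.39) or 2 (0.48). This call, adjusted p = 1.77e-06, held with an estimated correlation (adjusted p = 0.0381), though not when that array was also left out (adjusted p = 0.150 with an estimated correlation). Of 39 autophagy genes, 10 rose (10 higher and 1 lower adjusted over the list alone). They included Rragd (1.10), Fnip2 (0.69) and Fnip1 (0.54) of the lysosomal nutrient-sensing machinery and Uvrag (0.38). Adjusted p was 0.0146, and adjusted p = 0.425 with an estimated correlation, with 17 higher and 2 lower without that array.

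Markers of macrophages rose beside these lysosomal lists. Of 21 monocyte and lipid-associated macrophage markers, 18 rose and none fell, also adjusted over the list alone and without the array labelled WSB/EiJ PF-04287881 animal 3. Adjusted p was 5.88e-12, and adjusted p = 0.0944 with an estimated correlation. Of 19 Kupffer cell markers, 12 rose and 1, Nr1h3 (-0.10), fell (14 and 1 adjusted over the list alone, 12 and 2 without that array). Adjusted p was 5.11e-07, and adjusted p = 0.322 with an estimated correlation. The scavenger proteins Cd5l (1.12) and Timd4 (1.09), the complement receptor Vsig4 (0.99) and C1qb (0.94) rose most. Of 16 sinusoidal endothelial markers, 11 fell and none rose (12 lower and 1 higher adjusted over the list alone, 10 and 1 without that array). Gpr182 was at -0.66, Tek at -0.58, Oit3 at -0.50 and Fcgr2b at -0.47. Their adjusted p was 1.33e-05, and adjusted p = 0.425 with an estimated correlation. Hepatocyte markers, with 20 tested members, were not called (adjusted p = 0.975), and Ahsg (0.09) alone passed.

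**Figure D3:**
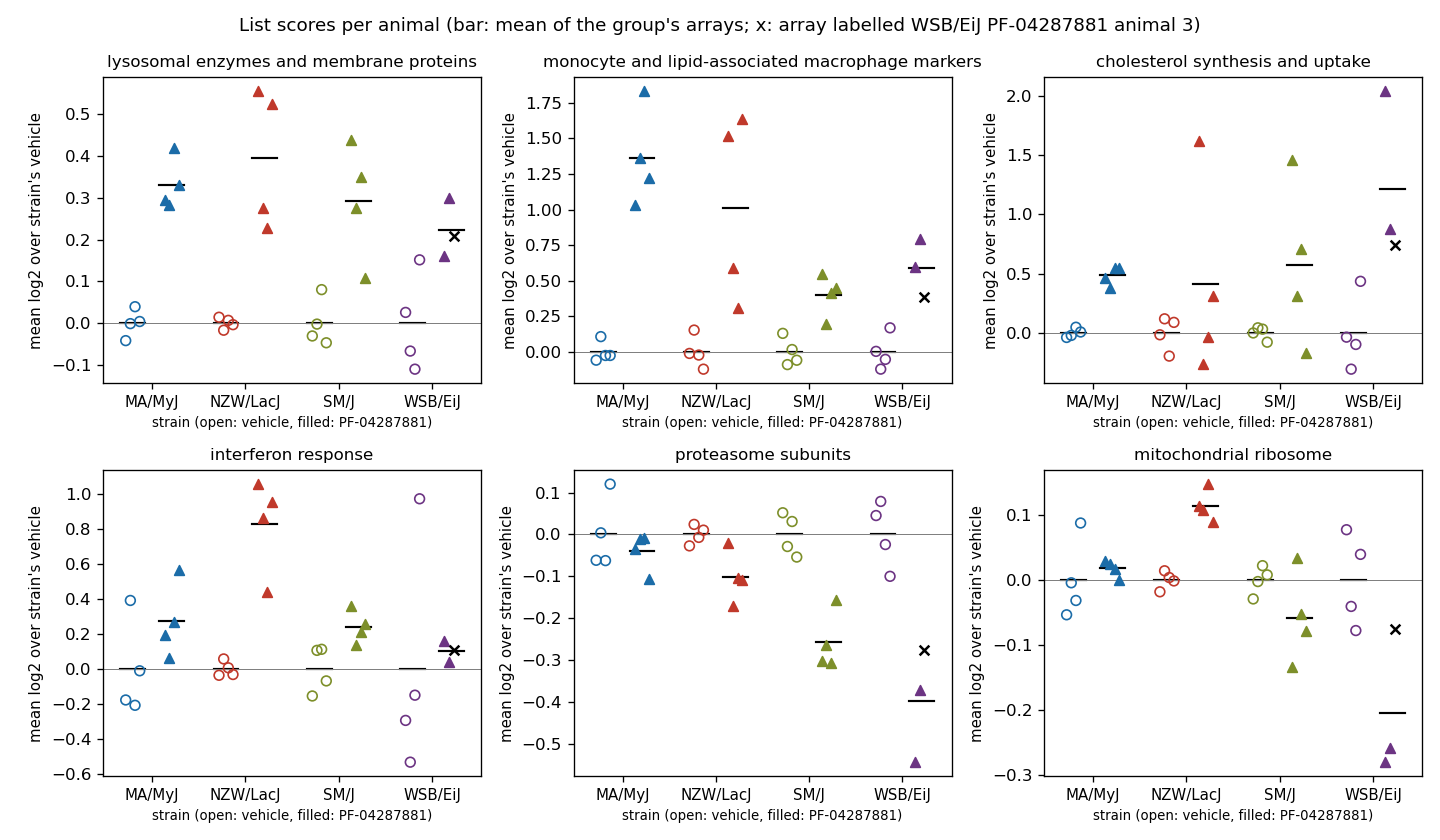
Scores of 6 gene lists in each animal, as the mean log2 difference of the list's members from the mean of the strain's vehicle animals (y axis), by strain and treatment (x axis). Open circles are vehicle animals, triangles PF-04287881 animals, crosses the array labelled WSB/EiJ PF-04287881 animal 3 and bars group means; for the monocyte and lipid-associated macrophage markers the treated MA/MyJ animals score 1.03 to 1.83 and the treated SM/J animals 0.20 to 0.54.

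Lists of immune and matrix genes were also called higher. Of 37 interferon response genes, 18 rose (22 adjusted over the list alone). The deubiquitinase Usp18 was at 1.23, the transcription factor Irf7 at 1.04, Ifi27l2a at 0.71 and Ifit2 at 0.70. The list gave adjusted p = 8.22e-07, and adjusted p = 0.425 with an estimated correlation, and without the array labelled WSB/EiJ PF-04287881 animal 3 it had 18 higher and 1 lower. The rise was uneven, with 2, 23 and 1 of the 37 genes higher in MA/MyJ, NZW/LacJ and SM/J. In WSB/EiJ Rsad2 (1.18) was higher and Gbp7 (-1.28), Iigp1 (-1.17), Stat2 (-0.99) and Ifi35 (-0.32) were lower. Of 6 genes of MHC class II presentation, H2-Ab1 (0.83), Cd74 (0.68), H2-Aa (0.66) and H2-Eb1 (0.54) rose, the same 4 adjusted over the list alone. That call (adjusted p = 0.0450, and adjusted p = 0.496 with an estimated correlation) was lost without any 1 of 11 animals, with adjusted p = 0.167 without that array. Of 22 inflammatory cytokines and chemokines, 7 rose (9 adjusted over the list alone, 11 higher and 1 lower without that array). They included Vcam1 (1.45), the endotoxin co-receptor Cd14 (0.85), Il18 (0.50) and Ccl5 (0.34). Adjusted p was 0.0126, and adjusted p = 0.425 with an estimated correlation. Cd14 lost its call without any 1 of 26 animals (0.65 to 0.87) and H2-Eb1 without any 1 of 17 (0.37 to 0.54). The rise of Cd14 rested on WSB/EiJ, at 3.74 without that array. Its effects of 0.61 in MA/MyJ, 0.03 in NZW/LacJ and 0.56 in SM/J did not pass in that fit. Of 30 acute phase proteins, 6 rose and Saa4 (-0.36) and Fga (-0.13) fell (7 and 2 adjusted over the list alone, 14 and 1 without that array). Orm2 (0.97), Lcn2 (0.91), Orm1 (0.57) and Apcs (0.54) rose most. Adjusted p was 0.0484, and adjusted p = 0.575 with an estimated correlation, and the call was lost without any 1 of 17 animals. Of 27 genes of extracellular matrix and fibrosis, 10 rose (11 adjusted over the list alone, 12 without that array). Among them were Mmp12 (1.46) and the matrix genes Col3a1 (0.94), Col4a1 (0.74) and Postn (0.59). Its adjusted p was 0.00410, and adjusted p = 0.575 with an estimated correlation.

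The list of cholesterol synthesis was called higher and that of fatty acid oxidation lower. Of 21 genes of cholesterol synthesis and uptake, 13 rose and none fell (13 adjusted over the list alone, 14 without the array labelled WSB/EiJ PF-04287881 animal 3). Cyp51 (1.55) and Nsdhl (1.53) led, followed by the squalene epoxidase Sqle (1.41) and Idi1 (1.39). Adjusted p was 1.12e-06, and adjusted p = 0.425 with an estimated correlation. The rise was uneven, with 2, 1, 1 and 11 of the 21 genes higher in MA/MyJ, NZW/LacJ, SM/J and WSB/EiJ. The list's score was 1.62 in NZW/LacJ treated animal 1 and -0.26, -0.04 and 0.31 in animals 2, 3 and 4. In SM/J it was 1.46 in treated animal 1 and 0.31, 0.71 and -0.17 in the others, in MA/MyJ it ran from 0.38 to 0.55, and in WSB/EiJ it was 2.04 and 0.87 in treated animals 1 and 2. Of 33 genes of fatty acid oxidation and PPAR alpha targets, 14 fell and Cpt1a (0.17) rose (15 and 1 adjusted over the list alone, 20 and 3 without that array). Acot2 was at -1.22, Fgf21 at -1.15, Acot1 at -1.06 and the pantetheinase Vnn1 at -0.94. Adjusted p was 2.62e-05, and adjusted p = 0.425 with an estimated correlation. In single strains 2, 5, 1 and 13 fell, in MA/MyJ, NZW/LacJ, SM/J and WSB/EiJ, and in NZW/LacJ Acot3 (1.28), Cpt1a (0.29) and Acadl (0.22) rose.

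Lists of proteasome, stress response and mitochondrial ribosome genes were called lower, and outside the proteasome most members did not pass. Of 38 proteasome subunits, 32 fell and Psmd8 (0.19) rose (32 and 2 adjusted over the list alone, 33 and 1 without the array labelled WSB/EiJ PF-04287881 animal 3). Each change was small, with Psmc1 at -0.38, Psmd1 at -0.36, Psmd7 at -0.34 and Psmb3 at -0.32. In single strains 1, 10, 17 and 32 of the 38 fell, in MA/MyJ (median -0.04), NZW/LacJ, SM/J and WSB/EiJ. The set test gave adjusted p = 7.38e-22, and adjusted p = 0.0876 with an estimated correlation. Of 37 genes of the unfolded protein and integrated stress response, 10 fell (12 adjusted over the list alone, 14 with 2 higher without that array). Among them were Fgf21 (-1.15), the chaperone-linked genes Creld2 (-0.80) and Manf (-0.63), and Atf5 (-0.41). Adjusted p was 0.00102, and adjusted p = 0.322 with an estimated correlation. Of 20 heat shock proteins and chaperones, 8 fell (11 lower and 1 higher adjusted over the list alone, 9 and 2 without that array). Hspa1b was at -0.86, Dnajb4 at -0.40, Hsp90aa1 at -0.33 and Dnaja1 at -0.30. Adjusted p was 0.0103, and adjusted p = 0.425 with an estimated correlation. In WSB/EiJ 7 fell (median -0.45), in MA/MyJ 1 and in SM/J 0, while in NZW/LacJ Hspe1 (0.32) rose, Hspa9 (-0.23) fell and the median was 0.18. Hsp90aa1 lost its call without any 1 of 15 animals (-0.33 to -0.25) and Dnajb4 without any 1 of 8 (-0.39 to -0.29). Of 24 genes of the NRF2 antioxidant response, 7 fell and Cbr3 (0.28) rose (9 and 1 adjusted over the list alone, 9 and 2 without that array). Glutathione reductase Gsr was at -0.58, the quinone reductase Nqo1 at -0.37 and the epoxide hydrolase Ephx1 at -0.36. Adjusted p was 0.00304, and adjusted p = 0.322 with an estimated correlation. In NZW/LacJ Abcc4 (1.18), Gstp1 (0.54) and Txnrd1 (0.43) rose and Gsr (-0.35) fell, with a median of 0.03. When WSB/EiJ was left out, Nqo1 was at 0.02. Of 72 genes of the mitochondrial ribosome, 11 fell and 4 rose, the same counts adjusted over the list alone (18 and 5 without that array). Mrps22 was at -0.33 and Mrpl49 at -0.29, against Mrps6 at 0.28, Mrpl27 at 0.26, Mrpl23 at 0.24 and Mrpl54 at 0.22. Its adjusted p was 0.0213, and adjusted p = 0.575 with an estimated correlation, and the call was lost without any 1 of 4 animals. The strains went opposite ways, with 27 lower and 0 higher in WSB/EiJ, 15 higher and 1 lower in NZW/LacJ (median 0.07), 3 and 2 in MA/MyJ and 0 and 1 in SM/J.

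Drug metabolism and the remaining pathway lists were not called in the average effect over all arrays. For CAR and PXR drug metabolism, whose genes respond to many foreign compounds, 7 of 41 rose and 13 fell (9 and 16 adjusted over the list alone). Cyp3a16 was at -0.99 and Alas1 at 0.83, and adjusted p was 0.0835. Without the array labelled WSB/EiJ PF-04287881 animal 3 this list was called lower (9 higher, 16 lower, adjusted p = 0.0290, and adjusted p = 0.512 with an estimated correlation). Of 25 p53 targets and apoptosis genes, Bid (0.55), Pmaip1 (0.55), Bak1 (0.37), Mcl1 (0.27) and Phlda3 (0.22) rose and Ccng1 (-0.17) fell (7 and 1 adjusted over the list alone), with adjusted p = 0.350. That list was called higher without that array (8 and 2, adjusted p = 0.0170, and adjusted p = 0.503 with an estimated correlation). Of 24 cell cycle genes, Ccnd1 (0.99), Mcm6 (0.93) and Stmn1 (0.55) rose, also adjusted over the list alone, with 5 higher without that array and adjusted p = 0.0583. Of 17 circadian clock genes, 7 rose and Arntl (-1.04), Clock (-0.45) and Npas2 (-0.44) fell, also adjusted over the list alone. Dbp was at 0.82, Usp2 at 0.68 and Bhlhe40 at 0.60, and adjusted p was 0.450. Fatty acid and triglyceride synthesis had 7 of 23 higher, with the lipogenic regulator Thrsp at 1.09, and Elovl3 (-1.54), Me1 (-0.76) and Agpat2 (-0.36) lower (8 and 3 adjusted over the list alone, adjusted p = 0.443). Of 25 genes of bile acid synthesis and transport, the uptake carrier Slco1a4 (0.69) and Abcg5 (0.43) rose and Cyp39a1 (-0.39), Hsd3b7 (-0.21), Klb (-0.19), Cyp27a1 (-0.17) and Slc27a5 (-0.10) fell, also adjusted over the list alone (adjusted p = 0.450).

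The AhR targets, 5 genes, had Ahr (0.29) higher and Nqo1 (-0.37) lower (3 and 1 adjusted over the list alone, adjusted p = 0.450). Ubiquitin conjugation had 8 of 44 genes higher and 8 lower (10 and 8 adjusted over the list alone, 12 and 8 without the array labelled WSB/EiJ PF-04287881 animal 3, adjusted p = 0.71). Of 59 nuclear subunits of oxidative phosphorylation, Atp5o (0.09), Cox6b1 (0.08), Cox7a2 (0.08) and Cox4i1 (0.07) rose and Ndufb5 (-0.10) and Ndufb9 (-0.08) fell, none of them when adjusted over the list alone (adjusted p = 0.840). Gluconeogenesis and fasting response had Lpin2 (0.56) and Cpt1a (0.17) higher and Fgf21 (-1.15), Cyp17a1 (-0.86) and Insig2 (-0.21) lower of 19. Glycolysis and glycogen had Gys2 (0.44) and Slc2a2 (0.18) higher and Ppp1r3c (-1.01) and Ldha (-0.13) lower of 16. Amino acid and urea metabolism had Glul (0.22) and Oat (0.14) higher and Cbs (-0.27) and Tdo2 (-0.15) lower of 23. Adjusted over the list alone these were 2 and 3, 3 and 2, and 2 and 2, with adjusted p of 0.975, 0.838 and 0.975. Without that array, gluconeogenesis had 6 higher and 3 lower, and amino acid metabolism 5 and 2.

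Of the other cell type markers, each not called, the neutrophil list (9 genes, adjusted p = 0.975) had Lcn2 (0.91) higher, and the T and NK cell list (8 genes, adjusted p = 0.331) had Ccl5 (0.34). The B and plasma cell list (9 genes, adjusted p = 0.975) had the adaptor Blnk (1.20) higher, and the erythroid list (6 genes, adjusted p = 0.838) had Car2 (0.32). These were the same single genes adjusted over the list alone. Stellate cell markers (16 genes, adjusted p = 0.975) had Cygb (0.26) higher and Ngfr (-0.19) lower, 1 and 0 adjusted over the list alone. Cholangiocyte markers (7 genes, adjusted p = 0.265) had Prom1 (0.86) higher, 2 genes adjusted over the list alone. Of 5 pancreas markers none passed, with Cela2a at 0.15 and Cela1 at -0.12 (adjusted p = 0.450). Of the 4 muscle and fat markers, too few for the set test, none passed, with Ckm at -0.43 and Car3 at 0.40. The median and the mean of the members lay on opposite sides of 0 for ubiquitin conjugation, bile acid synthesis and transport, gluconeogenesis and fasting response, and the neutrophil, B and plasma cell and hepatocyte markers. For stellate cell markers the test pointed lower while both lay above 0.

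In MA/MyJ, a strain coded for vacuolation, the largest rises included genes of lipid-laden macrophages. Gpnmb rose by 3.94 ± 0.51 (adjusted p = 3.89e-05, 4 treated and 4 vehicle animals), Mmp12 by 3.34 ± 0.46 and Lgals3 by 3.26 ± 0.39 (adjusted p = 1.71e-05). The estrogen sulfotransferase Sult1e1 rose by 2.78 ± 0.71 (adjusted p = 0.0235) and Clec7a, the beta-glucan receptor of macrophages, by 2.62 ± 0.31. The largest falls were those of Tcf24 (-1.89 ± 0.23), the carboxylesterase Ces1f (-1.73 ± 0.31), the laminin subunit Lamb3 (-1.40 ± 0.40), Asic5 (-1.32 ± 0.23) and Akr1c19 (-1.31 ± 0.35).

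Among MA/MyJ gene groups, 13 of 21 monocyte and lipid-associated macrophage markers rose (14 adjusted over the list alone), with Cd68 at 2.57. Of 19 Kupffer cell markers 9 rose (12 adjusted over the list alone), with C1qb at 1.43, Cd5l at 1.39, Vsig4 at 1.38 and Il18bp at 1.33. Of 51 lysosomal genes 14 rose (23 higher and 3 lower adjusted over the list alone). Of 27 genes of phospholipid breakdown 7 rose (9 adjusted over the list alone), with Pla2g7 at 1.92 and Lpl at 1.82. Of 21 cholesterol genes, Nsdhl (1.66) and Dhcr7 (1.58) rose. In CAR and PXR drug metabolism, Gstm2 (1.46) and Slco1a4 (0.76) rose and Cyp2c29 (-0.97), Ces2a (-0.90), Ces1d (-0.79), Gstm1 (-0.49) and Cyp2c38 (-0.42) fell of 41 (5 and 6 adjusted over the list alone). In all, 534 genes passed, 408 higher and 126 lower, and 941 without the array labelled WSB/EiJ PF-04287881 animal 3, which adds to the spread shared by all groups. With array weights the count was 2607. It was 305 without vehicle animal 1, 329 without vehicle animal 2, 305 without vehicle animal 3, 329 without treated animal 2, 279 without treated animal 3 and 329 without treated animal 4. Sult1e1 lost its call without treated animal 2 (2.39) or 4 (2.67) or vehicle animal 1 (2.44) or 3 (2.77), Lamb3 without any 1 of 12 animals (-1.48 to -1.07) and Akr1c19 without any 1 of 5 (-1.32 to -1.15).

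In NZW/LacJ, coded for vacuolation and for necrosis, the largest rises included the macrophage gene Gpnmb, the cyclin gene Ccnd1 and the interferon response gene Usp18. Gpnmb rose by 2.76 ± 0.51 and Ccnd1, the cyclin that drives entry into the cell cycle, by 2.66 ± 0.42 (adjusted p = 5.31e-05, 4 treated and 4 vehicle animals). Uap1l1 rose by 2.4 ± 0.25 (adjusted p = 4.69e-07), Usp18 by 2.33 ± 0.48 and the reductase Ptgr1 by 2.21 ± 0.28. The clock activator Arntl fell by 2.83 ± 0.29 (adjusted p = 4.37e-07), Elovl3 by 2.79 ± 0.48, the urinary protein gene Mup10 by 2.66 ± 0.60, Acot1 by 2.13 ± 0.33 and the CAR target Cyp2b10 by 2.10 ± 0.61.

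Among NZW/LacJ gene groups, 23 of 37 interferon response genes rose (24 adjusted over the list alone), with Usp18 at 2.33, Gbp7 at 2.04, Irf7 at 1.89 and Rtp4 at 1.44. Adjusted p was 2.60e-08, and adjusted p = 0.851 with an estimated correlation. Of 51 lysosomal genes 26 rose (32 higher and 1 lower adjusted over the list alone). Of 16 vacuolar ATPase subunits 10 rose (11 adjusted over the list alone), and of 21 monocyte and lipid-associated macrophage markers 13 rose (17 adjusted over the list alone). The markers gave adjusted p = 2.19e-05, and adjusted p = 0.851 with an estimated correlation. Of 19 Kupffer cell markers 4 rose (9 adjusted over the list alone, 7 without the array labelled WSB/EiJ PF-04287881 animal 3). Of 24 cell cycle genes 7 rose, also adjusted over the list alone, among them Ccnd1 and the replication factors Mcm6 (1.64) and Mcm2 (1.58), in a list not called (adjusted p = 0.0992, and adjusted p = 0.851 with an estimated correlation). In CAR and PXR drug metabolism 11 of 41 fell and Alas1 (2.12), Slco1a4 (0.84) and Abcc3 (0.64) rose (12 and 4 adjusted over the list alone), with Cyp3a16 at -1.87 and Cyp3a44 at -1.68. Of 38 proteasome subunits 10 fell (12 adjusted over the list alone). In all, 2766 genes passed, 1941 higher and 825 lower, and 3436 without the array labelled WSB/EiJ PF-04287881 animal 3.

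In SM/J, coded for neither finding, the glucuronosyltransferase Ugt2b37 rose by 2.22 ± 0.57 (adjusted p = 0.0340, 4 treated and 4 vehicle animals) and Ifi27l2b by 2.09 ± 0.22 (adjusted p = 4.30e-06). Eppk1 rose by 1.86 ± 0.33, the ubiquitin-like Ubd by 1.83 ± 0.28 and the lipid-binding Osbpl3 by 1.81 ± 0.23. Hao2, a peroxisomal oxidase, fell by 2.28 ± 0.60 (adjusted p = 0.0390), Lamb3 by 1.97 ± 0.40, Ppp1r3c by 1.47 ± 0.40, the clock repressor Nr1d1 by 1.43 ± 0.35 and Slc30a10 by 1.25 ± 0.20.

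Among SM/J gene groups, 17 of 38 proteasome subunits fell (30 lower and 1 higher adjusted over the list alone), with Psmd1 at -0.53 and Psmc1 at -0.49. Of 51 lysosomal genes 9 rose (25 adjusted over the list alone, 16 without the array labelled WSB/EiJ PF-04287881 animal 3), with Cd68 at 1.61, Arsa at 0.74, Galns at 0.71 and the ceramidase Asah1 at 0.47. The acute phase proteins Orm2 (1.56), Orm1 (0.97), Apcs (0.73), Hamp (0.33) and Hpx (0.24) rose of 30 (7 adjusted over the list alone). The endothelial markers Flt4 (-0.76) and Ptprb (-0.50) fell of 16 (10 adjusted over the list alone). In all, 334 genes passed, 206 higher and 128 lower, and 600 without the array labelled WSB/EiJ PF-04287881 animal 3. With array weights the count was 2765. The count was 207, 179, 166 and 155 without vehicle animals 1, 2, 3 and 4, and 103, 206 and 119 without treated animals 1, 2 and 3. Ugt2b37 and Nr1d1 lost their calls without any 1 of 7 SM/J animals (2.36 to 2.0 and -1.54 to -1.27), Hao2 without any 1 of 6 (-2.49 to -1.95) and Ppp1r3c without any 1 of 22 animals (-1.58 to -1.26).

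In WSB/EiJ, also coded for neither finding, values depended on the array labelled WSB/EiJ PF-04287881 animal 3. Cyp51 rose by 3.11 ± 0.63 with 3 treated and 4 vehicle arrays and by 3.89 ± 0.64 without that array, and Nsdhl by 2.49 ± 0.48 and by 3.03. The retinol dehydrogenase Rdh9 rose by 2.87 ± 0.21 (adjusted p = 3.06e-09) and by 2.89 without it, and Ugt2b37 by 2.50 ± 0.62 and by 2.14. Ugt3a2 was at 2.76 ± 0.72 with that array and at 0.84 without it. Ncbp2, of the nuclear cap-binding complex, fell by 2.60 ± 0.55 and, without that array, by 3.96 ± 0.25 (adjusted p = 4.27e-11). Meiob (-2.52 ± 0.40), Crebzf (-2.41 ± 0.35), Fgf21 (-2.39 ± 0.56) and Stxbp6 (-2.33 ± 0.48) also fell, and lay at -3.16, -3.26, -3.27 and -3.49 without that array. The 5 largest rises without that array were Cyp51, the endotoxin co-receptor Cd14 (3.74 ± 0.36), the endothelial clotting factor Vwf (3.69 ± 0.25), the glycogen-targeting subunit Ppp1r3g (3.68 ± 1.15) and the muscle ubiquitin ligase Trim63 (3.45 ± 0.49). With it, Cd14 was at 2.19, Vwf at 2.43, Ppp1r3g at 1.46 and Trim63 at 1.59, the last 2 not past the threshold.

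Among WSB/EiJ gene groups, 32 of 38 proteasome subunits fell with and without the array labelled WSB/EiJ PF-04287881 animal 3 (33 adjusted over the list alone), with Psma1 at -0.94, Psmd14 at -0.73, Psma3 at -0.70 and Psmc2 at -0.67. Of 72 mitochondrial ribosome genes 27 fell (31 lower and 3 higher adjusted over the list alone), with Mrps22 at -0.70 and Mrpl49 at -0.63, and 38 fell and 1 rose without that array. Of 21 cholesterol genes 11 rose (14 adjusted over the list alone, 14 without that array), with Fdps at 2.46 and Tm7sf2 at 1.64 behind Cyp51 and Nsdhl. Of 33 fatty acid oxidation genes 13 fell (16 adjusted over the list alone, 19 with 1 higher without that array), with Fgf21, Vnn1 at -2.09, Acot2 at -1.43 and Eci1 at -1.15. Of 24 NRF2 genes 7 fell and Cbr3 (0.50) rose, with Nqo1 at -1.52, Nfe2l2 at -1.20 and Gsr at -0.89 (8 lower and 1 higher adjusted over the list alone), and 10 fell and 1 rose without that array. Nfe2l2 reversed, to 0.40 with adjusted p = 0.219, when all of its probe sets were averaged. Of 51 lysosomal genes 17 rose and Ids (-0.80), Acp2 (-0.79), Gaa (-0.37) and Lamp2 (-0.29) fell (20 and 5 adjusted over the list alone, 22 and 5 without that array). Of 19 Kupffer cell markers 9 rose and Slc40a1 (-0.52) and Nr1h3 (-0.45) fell (11 and 2 adjusted over the list alone), with Timd4 at 1.72 and Vsig4 at 1.48. Adjusted p was 7.60e-20 for the proteasome, 1.86e-07 for the mitochondrial ribosome, 1.86e-07 for cholesterol synthesis and 0.00558 for NRF2 genes, and adjusted p = 0.339, 0.504, 0.504 and 0.504 with an estimated correlation. In all, 2488 genes passed, 891 higher and 1597 lower. The count was 4180 without that array, 1784 higher and 2396 lower with 2114 shared, and 1282 without treated animal 1. With the WSB/EiJ arrays alone, whose spread then includes no other strain, 4 genes passed, or 990 without that array. In the 4 strains together, 67 of 173 named changes lost their call when only the arrays of the strain were used.

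The effect of the drug differed among the strains for 2498 genes by the moderated F test, and for 4180 without the array labelled WSB/EiJ PF-04287881 animal 3, with 2355 shared. When NZW/LacJ was left out the count was 685. Across genes, which are not independent replicates, the effects in MA/MyJ and NZW/LacJ had a Pearson correlation of 0.48, with 265 genes higher in both against 61.4 expected from the separate counts. The correlation was 0.46 for MA/MyJ with SM/J, 0.41 for NZW/LacJ with SM/J, 0.30 for SM/J with WSB/EiJ and 0.15 for MA/MyJ with WSB/EiJ. NZW/LacJ and WSB/EiJ were at -0.04, with 523 genes called in opposite directions against 298 expected, and at 0.03 with 758 against 588 without that array. The cyclin gene Ccnd1 is an example, at 2.66 in NZW/LacJ and -1.29 in WSB/EiJ.

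The vacuolation contrast asks which drug effects followed the vacuolation of Kupffer cells. Gpnmb rose more in the vacuolation strains, by 2.79 ± 0.52 (adjusted p = 0.000568, 8 treated and 8 vehicle arrays against 7 and 8 as labelled), with effects of 3.94 in MA/MyJ, 2.76 in NZW/LacJ, 0.57 in SM/J and 0.55 in WSB/EiJ. Without the array labelled WSB/EiJ PF-04287881 animal 3 its WSB/EiJ effect was 1.15 and the contrast 2.49. Ccnd1 differed by 2.71 ± 0.42 (adjusted p = 9.04e-05), with effects of 2.03, 2.66, 0.55 and -1.29 in the same order. Mmp12 differed by 2.10 ± 0.47. The serine synthesis enzyme Psat1 went the other way, at -1.79 ± 0.41, with effects of -1.15, -1.02, 0.43 and 0.98.

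Further genes with higher effects in the vacuolation strains were Sult1e1 (2.22 ± 0.73, and 1.36 without the array labelled WSB/EiJ PF-04287881 animal 3), the adaptor Stap1 (1.95 ± 0.35), and the mitochondrial transcription factor Mterf2 (1.80 ± 0.19, adjusted p = 1.40e-06). They also included the interferon-inducible GTPase Gbp7 (1.77 ± 0.34), Them7 (1.64 ± 0.26), Stxbp6 (1.62 ± 0.46) and the kinase Ikbke (1.58 ± 0.25). Stxbp6 did not pass in MA/MyJ (0.04) or NZW/LacJ (0.52), and its contrast rested on a fall in WSB/EiJ (-2.33). Over all arrays, Stap1 (0.54), Gbp7 (0.52) and Them7 (0.72) did not pass in MA/MyJ either. They rose in NZW/LacJ (1.09, 2.04 and 0.96) and fell in WSB/EiJ (-1.72, -1.28 and -1.35). Lower effects were found for Mup10 (-2.10 ± 0.61, and -1.50 without that array), Bmper, a regulator of BMP signalling (-2.10 ± 0.30), Ugt2b37 (-2.0 ± 0.59) and the uptake carrier Slco1a1 (-1.77 ± 0.38). They were also found for Nnmt (-1.68 ± 0.49), the desaturase Scd1 (-1.44 ± 0.37), the clock repressor Cry1 (-1.40 ± 0.26), Slc22a30 (-1.33 ± 0.37) and Fam25c (-1.30 ± 0.40, and -0.87 without that array). Over all arrays, Slco1a1 (2.18), Slc22a30 (1.36) and Fam25c (1.22) passed in WSB/EiJ alone, as higher. None of the genes named with lower effects passed in MA/MyJ over all arrays. Gbp7, Mup10, Bmper, Ugt2b37, Slco1a1 and Nnmt are named again in the necrosis contrast, which shares NZW/LacJ. The WSB/EiJ effect of Mup10 was 0.62, and -0.59 without that array. The call of Sult1e1 was lost without any 1 of 10 animals, at 2.02 without MA/MyJ treated animal 2.

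Of the lists, 22 of 38 proteasome subunits had higher effects in the vacuolation strains and none lower (23 adjusted over the list alone, 23 without the array labelled WSB/EiJ PF-04287881 animal 3). Psmd14 was at 0.62, Psma3 at 0.62, Psma1 at 0.61 and Psmd2 at 0.46. A higher effect here does not mean a rise. As given above, more subunits fell in WSB/EiJ and SM/J than in NZW/LacJ and MA/MyJ. The list gave adjusted p = 2.30e-09, and adjusted p = 0.908 with an estimated correlation. Of 72 mitochondrial ribosome genes 27 were higher and Mrps23 (-0.25) lower (30 and 2 adjusted over the list alone, 33 and 1 without that array), with Mrps15 at 0.65 and Mrpl1 at 0.61. Adjusted p was 7.57e-07, and adjusted p = 0.908 with an estimated correlation. As given above, the ribosome genes that passed mostly rose in NZW/LacJ and fell in WSB/EiJ, while few passed in MA/MyJ or SM/J. Of 21 monocyte and lipid-associated macrophage markers 7 were higher, also adjusted over the list alone, among them Gpnmb (2.79), Mmp12 (2.10), Lpl (1.44) and Lgals3 (1.34). The call (adjusted p = 0.0170, and adjusted p = 0.970 with an estimated correlation) was lost without that array, at adjusted p = 0.0514. Of 37 interferon genes 6 were higher, also adjusted over the list alone, among them Gbp7 (1.77), the immunoproteasome subunit Psmb9 (1.27), Ifih1 (0.81) and Ifi35 (0.67). Adjusted p was 0.0296, and adjusted p = 0.970 with an estimated correlation. Without that array 9 were higher and the call was lost, at adjusted p = 0.0514. It was lost without any 1 of 10 animals, most clearly without WSB/EiJ vehicle animal 4 (median 0.28 against 0.48, adjusted p = 0.204, and adjusted p = 0.914 with an estimated correlation), whose interferon score of 0.97 was the highest of the WSB/EiJ vehicle animals. Of 21 cholesterol genes, Tm7sf2 (-0.82), Hsd17b7 (-0.58) and Ebp (-0.22) were lower and Srebf2 (0.36) higher, also adjusted over the list alone, and 6 were lower and 1 higher without that array. Adjusted p was 0.0177, and adjusted p = 0.970 with an estimated correlation, and the call was lost without any 1 of 3 animals. The lysosomal list was not called (9 higher, Galns at -0.36 lower, adjusted p = 0.354), nor were the Kupffer cell markers (Nr1h3 higher at 0.37, adjusted p = 0.705).

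In all, 2194 genes passed in the vacuolation contrast, 1617 higher and 577 lower. Of these, 1888 (86.1%) had both vacuolation strains on the same side of both others, an order that the contrast itself favours. The count was 3390 without the array labelled WSB/EiJ PF-04287881 animal 3, 2074 of them shared, 315 when NZW/LacJ was left out and 938 when WSB/EiJ was left out. Of the 39 lists, 5 were called, 6 without that array and 3 without NZW/LacJ treated animal 2. Only 3 were called with and without that array. Without it, acute phase proteins (adjusted p = 0.0145) and inflammatory cytokines and chemokines (adjusted p = 0.0456) were also called lower and oxidative phosphorylation (adjusted p = 0.00758) higher, each with adjusted p = 0.935 with an estimated correlation.

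The necrosis contrast asks which drug effects set NZW/LacJ, the strain with single cell necrosis, apart. Il1rn, the interleukin 1 receptor antagonist, differed by 2.26 ± 0.39 (adjusted p = 0.000251, 4 treated and 4 vehicle arrays against 11 and 12 as labelled), with effects of 1.64 in NZW/LacJ, -0.24 in MA/MyJ, 0.19 in SM/J and -1.82 in WSB/EiJ. Ccnd1 differed by 2.23 ± 0.48 and Gbp7 by 2.19 ± 0.39. Arntl differed by -2.39 ± 0.34 (adjusted p = 3.48e-05) and Elovl3 by -1.67 ± 0.56 (adjusted p = 0.0438).

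The effect was also higher in NZW/LacJ for Pcp4l1 (1.90 ± 0.33), the transcription factor Bach2 (1.88 ± 0.41) and the ceramide synthase Cers6 (1.84 ± 0.30). It was also higher for the oxidase Aox1 (1.83 ± 0.36), Acot3 (1.79 ± 0.45), Gbp6 (1.76 ± 0.57) and the transglutaminase Tgm1 (1.76 ± 0.28). Lower effects were found for Mup10 (-2.50 ± 0.69), Ugt2b37 (-2.36 ± 0.67), Bmper (-2.06 ± 0.34), and the lipid transporter Abca6 (-2.02 ± 0.40). They were also found for Nnmt (-1.95 ± 0.56), Rprd2 (-1.87 ± 0.35), Slco1a1 (-1.65 ± 0.44) and Tspyl4 (-1.64 ± 0.36). In NZW/LacJ itself Aox1 (0.55), Gbp6 (1.35), Ugt2b37 (-0.41) and Slco1a1 (-0.87) did not pass. Aox1 fell in WSB/EiJ (-2.19), Ugt2b37 rose in SM/J (2.22) and WSB/EiJ (2.50), and Slco1a1 rose in WSB/EiJ (2.18). The contrast of Mup10 was -2.10 without the array labelled WSB/EiJ PF-04287881 animal 3. Without NZW/LacJ treated animal 3 the calls of Mup10 (-2.01) and Ugt2b37 (-1.77) were lost, without treated animal 1 that of Nnmt (-1.68), and without vehicle animal 1 that of Ugt2b37 (-2.07). Elovl3 lost its call without any 1 of 19 animals (-1.79 to -1.30) and Gbp6 without any 1 of 10 (1.57 to 1.84).

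Of the lists, 7 of 37 interferon response genes had a higher effect in NZW/LacJ (10 adjusted over the list alone, 8 without the array labelled WSB/EiJ PF-04287881 animal 3), with Gbp7 at 2.19, Psmb9 at 1.32, Oas1a at 1.07 and Psmb10 at 1.03. Adjusted p was 0.000130, and adjusted p = 0.944 with an estimated correlation. The call stayed without each of the 31 animals, with a median of 0.50 against 0.62 without WSB/EiJ vehicle animal 4. Of 72 mitochondrial ribosome genes 19 were higher (24 adjusted over the list alone, 27 with 1 lower without that array), with Mrps6 at 0.83 and Mrpl1 at 0.63. Adjusted p was 0.000118, and adjusted p = 0.944 with an estimated correlation. Of 23 genes of amino acid and urea metabolism, Kynu (-0.94), Asl (-0.41) and Tdo2 (-0.36) were lower (5 adjusted over the list alone, 4 without that array). Adjusted p was 0.000814, and adjusted p = 0.944 with an estimated correlation. Of 23 genes of fatty acid and triglyceride synthesis, Elovl3 (-1.67) and Dgat1 (-0.47) were lower (6 adjusted over the list alone, 3 without that array). Adjusted p was 0.0314, and adjusted p = 0.944 with an estimated correlation. Of 38 proteasome subunits 8 were higher (10 higher and 2 lower adjusted over the list alone, 12 higher without that array), with Psma1 at 0.49 and Psma3 at 0.42. Adjusted p was 0.0492, and adjusted p = 0.944 with an estimated correlation, and the call was lost without any 1 of 16 animals. In NZW/LacJ itself some proteasome subunits fell and, as given above, more fell in SM/J and WSB/EiJ.

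In all, 1947 genes passed in the necrosis contrast, 1457 higher and 490 lower. Of these, 1929 (99.1%) had the NZW/LacJ effect beyond all others, which is likewise favoured by the contrast. The count was 2804 without the array labelled WSB/EiJ PF-04287881 animal 3, 1935 of them shared. Of the 39 lists 5 were called, 6 without that array, 3 without NZW/LacJ treated animal 3 and 8 without treated animal 4. All 5 were also called without that array, with cholesterol synthesis as the sixth (lower, adjusted p = 0.0352, and adjusted p = 0.935 with an estimated correlation).

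Vehicle levels show how the strains differed before any drug. The inflammasome gene Nlrp12 was higher in vehicle animals of the vacuolation strains by 3.50 ± 0.32 (adjusted p = 9.11e-09, 8 against 8 animals). So were Mup10 (3.46 ± 0.42), the interferon-inducible Mndal (3.37 ± 0.36), Ugt3a2 (3.36 ± 0.47), the oxidase Nox4 (3.10 ± 0.35) and the steroid dehydrogenase Hsd3b2 (3.09 ± 0.47). The steroid hydroxylase Cyp17a1 (-3.07 ± 0.36), the glutathione transferase Gstm2 (-2.62 ± 0.17, adjusted p = 2.94e-11), Bex4 (-2.17 ± 0.29), Slc4a9 (-2.15 ± 0.29), Bex1 (-2.11 ± 0.45) and Btg2 (-1.99 ± 0.48) were lower. Of 38 proteasome subunits 24 were lower and Psme1 (0.44), Psmb6 (0.25) and Psme4 (0.21) higher (27 and 3 adjusted over the list alone). In all, 1539 genes were higher and 1705 lower, 3244 in all, and 4024 passed without the array labelled WSB/EiJ PF-04287881 animal 3, which alters the spread here and no vehicle mean.

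NZW/LacJ vehicle animals stood apart from the other strains with Hsd3b5 higher by 4.99 ± 0.52 (adjusted p = 1.39e-07, 4 against 12 animals), the microsomal transferase Mgst2 by 4.83 ± 0.43 and the adipokine Serpina12 by 3.94 ± 0.55. The prostaglandin synthase Ptgds was higher by 3.42 ± 0.28, the succinate receptor Sucnr1 by 3.40 ± 0.53 and Akr1c18 by 3.19 ± 0.30. Abhd1 (-3.83 ± 0.24, adjusted p = 3.11e-11), Cyp2c23 (-3.58 ± 0.36), Akr1c12 (-3.08 ± 0.25), Cyp17a1 (-2.76 ± 0.42), Dcakd (-2.72 ± 0.19) and Tdrp (-2.67 ± 0.32) were lower. Of 19 Kupffer cell markers 10 were higher and Nr1h3 (-0.40) lower, also adjusted over the list alone, with Cd5l at 1.05, Timd4 at 1.00, Folr2 at 0.96 and Csf1r at 0.96. Of 38 proteasome subunits 26 were lower (27 lower and 1 higher adjusted over the list alone). Of 33 fatty acid oxidation genes 15 were lower and Cyp4a31 (1.99) higher, with Pdk4 at -2.43. Of 21 cholesterol genes 8 were higher and Srebf2 (-0.38) lower, with Sc5d at 1.62 and Msmo1 at 1.34, both the same adjusted over the list alone. In all, 3685 genes passed, 1501 higher and 2184 lower, and 4404 without the array labelled WSB/EiJ PF-04287881 animal 3. Probe sets that lie over strain variants can give false differences of this kind between strains.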

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

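All tests of explanations and all counts of other splits in this part were chosen after the result they bear on was seen, except the count of splits of WSB/EiJ without the array labelled WSB/EiJ PF-04287881 animal 3.

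The array labelled WSB/EiJ PF-04287881 animal 3 stood apart from the other WSB/EiJ arrays. A WSB/EiJ animal that did not respond to the drug is argued against by a position of 0.000305 on probe sets private to WSB/EiJ, where the other WSB/EiJ arrays lay between 0.970 and 1.05, with vehicle animal 4 at 0.777, and a mixture of RNA of both strains by a position of 1.03 on those private to NZW/LacJ. An exchange with an array labelled NZW/LacJ is argued against as well, since 0 of 8 such arrays sat with WSB/EiJ. RNA of a vehicle-treated NZW/LacJ animal under a WSB/EiJ label remains a candidate explanation, with a position of 0.0266 between vehicle (0) and treated (1) NZW/LacJ animals. The array correlated most with NZW/LacJ vehicle animal 1, at 0.9964, against 0.9946 to 0.9961 between pairs of NZW/LacJ vehicle arrays. Where such RNA came from stays open, because each of the 8 NZW/LacJ arrays sat with its own strain.

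Lysosomal genes rose together with macrophage markers, and the lysosomal score without macrophage markers rose by 0.26 (SE 0.0340) on average without that array. A lower share of hepatocytes would raise the markers of every other cell type, and sinusoidal endothelial markers went the other way, at -0.28 (SE 0.0848) against 0.87 (SE 0.110) for monocyte and lipid-associated macrophage markers. That comparison assumes that endothelial genes kept their level per cell, which was not tested, so a lower share of hepatocytes is not excluded. The score of hepatocyte markers itself was at 0.0059 (SE 0.0123) on average without that array. More macrophages with unchanged lysosomal levels per cell, in the same proportion in every strain, would give SM/J a lysosomal rise of 0.0668 from its Kupffer cell markers, where 0.26 was measured. The difference of 0.196 (SE 0.0967), or 0.206 (SE 0.0746) from monocyte markers, lies only about 2 standard errors or somewhat more above 0, so this rests on a small margin. These standard errors treat the lysosomal and marker scores as independent, though both come from the same animals, so the true margin can differ. Only SM/J was compared in this way. Kupffer cell markers and the lysosomal score rose by 0.76 and 0.26 in MA/MyJ, 0.45 and 0.36 in NZW/LacJ, and 0.71 and 0.17 in WSB/EiJ. At a like rise of these markers, WSB/EiJ thus showed no larger lysosomal rise than MA/MyJ. A change in lysosomal genes within hepatocytes or within macrophages, as the vacuolation coded for MA/MyJ and NZW/LacJ might involve, and macrophage numbers that differ from strain to strain in another proportion, stay open.

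Other divisions of the arrays into groups of the same sizes were tested for each count. The real labels gave the largest count for MA/MyJ (534 genes, at most 9 in another split, 1 of 35 splits as large), NZW/LacJ (2766, at most 2, 1 of 35) and SM/J (334, at most 3, 1 of 35). It was also excluded for the average effect (2859, at most 1623, 1 of 100 splits drawn) and for the F test (2498, at most 365, 1 of 100). For the lists of the average effect 19 were called, against at most 20 in another split, and 3 of 100 splits were as large. Since the other splits called a median of 9 lists, many such calls arise without the real labels, and chance is not excluded for single lists. For WSB/EiJ the splits did not argue against chance, with 2488 genes and 4 of 35 splits as large. The largest other split, at 4267, set vehicle animal 3 and treated animals 1 and 2 against the rest. Other splits that call more genes than the real one point to a structure among the arrays labelled WSB/EiJ. Without the array labelled WSB/EiJ PF-04287881 animal 3 there were too few splits for a share under 0.05, with 4180 genes, up to 3470 in another split and 1 of 15 as large.

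The strain contrasts also had too few splits for a share under 0.05. The real and the highest other value were 2194 and 989 for the vacuolation contrast (1 of 3 as large), 1947 and 2556 for the necrosis contrast (2 of 4), 3244 and 4402 for vehicle levels by vacuolation (2 of 3), 3685 and 4954 by necrosis (2 of 4), and for the lists 5 and 6 by vacuolation (2 of 3) and 5 and 7 by necrosis (3 of 4).

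The drug effect differed between strains for 2498 genes by the F test, 2194 in the vacuolation contrast and 1947 in the necrosis contrast. Medians of lists called in the vacuolation contrast were -0.49 for cholesterol synthesis and uptake, 0.18 for the mitochondrial ribosome, 0.28 for proteasome subunits, 0.48 for the interferon response, and 0.49 for monocyte and lipid-associated macrophage markers, and none of these calls held with an estimated correlation. In the necrosis contrast they were -0.23 for fatty acid and triglyceride synthesis, -0.17 for amino acid and urea metabolism, 0.14 for proteasome subunits, 0.14 for the mitochondrial ribosome and 0.62 for the interferon response, again with no call held with an estimated correlation.

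Outside the gene comparisons, 382 of 3344 tested probe sets without 1 gene name passed in the average effect, 194 higher and 188 lower, and 595 passed without the array labelled WSB/EiJ PF-04287881 animal 3.

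In 8 of 133 groups (19 called lists in 7 groups of 4 animals), the gap between the extreme animal's score and the nearest other took up most of the group's range, where about 1 group in 20, or 6.65, would by chance. The share was 0.849 for vacuolar proton ATPase in WSB/EiJ vehicle animal 2 (highest), 0.893 for heat shock proteins and chaperones in NZW/LacJ vehicle animal 3 (lowest), and 0.884 for the NRF2 antioxidant response in MA/MyJ vehicle animal 2 (highest). For the unfolded protein and integrated stress response it was 0.831 in NZW/LacJ vehicle animal 1 (lowest) and 0.844 in SM/J vehicle animal 1 (highest). It was 0.900 for acute phase proteins in MA/MyJ treated animal 3 (lowest), and for extracellular matrix and fibrosis 0.894 in WSB/EiJ vehicle animal 3 and 0.882 in SM/J vehicle animal 2 (both lowest).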

How the results depend on the processing

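Of 569 alternative values of the 13 counts of genes and lists, 503 lay within 1.5 times the count reported. For each count, 31 of these values left out a single animal, so the share speaks mainly to that change. Of 4167 alternative values of named genes outside the omission of single animals, 3855 kept their direction and their side of the threshold, 298 kept the direction alone and 12 newly passed. Only 2 reversed. Nfe2l2 in WSB/EiJ went to 0.40 with the mean of all its probe sets, and Nqo1 in the average effect to 0.018 without WSB/EiJ. The cause was not tested. The alternatives that leave out the array labelled WSB/EiJ PF-04287881 animal 3 together with another change were chosen after seeing the data, and the rest were planned.

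A fold minimum of 1.5, which by its construction can only shorten a count, left 236 genes in MA/MyJ, 947 in NZW/LacJ, 136 in SM/J, 1022 in WSB/EiJ, 295 in the average effect, 685 and 817 in the vacuolation and necrosis contrasts, and 666 and 952 in the corresponding vehicle levels. With that array also left out these were 326, 1047, 199, 2014 (within 1.5 times), 398, 1058, 1094, 711 and 1014. Array weights, which gave that array 0.0822 against at least 0.232 for any other, raised the counts to 2607 in MA/MyJ, 4418 in NZW/LacJ, 2765 in SM/J, 4209 in WSB/EiJ, 5280 in the average effect, 4432 and 3634 in the contrasts, 5112 and 6336 in the vehicle levels and 5859 in the F test. The cause was not tested. With the arrays of a strain alone, MA/MyJ had 1063 genes and WSB/EiJ 4, or 990 without that array. Without NZW/LacJ, and so with fewer animals and another contrast, the average effect had 1768 genes, the vacuolation contrast 315, its vehicle level 2081 and the F test 685. Without WSB/EiJ the average effect had 4444 and the vacuolation contrast 938. With an estimated correlation, 1, 0 and 0 lists were called in the average effect and the vacuolation and necrosis contrasts, and 0, 0 and 0 with that array also left out. The vacuolation lists fell to 3 without SM/J and the necrosis lists to 3 after another quantile normalisation, and the cause was not tested.

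Leaving out each animal in turn gave 279 to 941 genes in MA/MyJ, 2052 to 3436 in NZW/LacJ, 103 to 600 in SM/J, 1282 to 4180 in WSB/EiJ, 2527 to 4209 in the average effect, 1824 to 3390 in the vacuolation contrast, 1463 to 2804 in the necrosis contrast, 2851 to 4024 and 2759 to 4404 in the vehicle levels, and 2115 to 4180 in the F test. The highest gene count came in each case without the array labelled WSB/EiJ PF-04287881 animal 3. The lists numbered 16 to 20, 3 to 6 and 3 to 8. Among 400 named changes, 6 to 34 lost their call when a single animal was left out, and none reversed.

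The balance of higher and lower genes moved by over 10 percentage points with another quantile normalisation, to 1626 higher and 1130 lower in NZW/LacJ, 1354 and 819 in the vacuolation contrast and 1206 and 685 in the necrosis contrast. The animal numbers of the labels did not pair the animals, since residuals of the same number correlated between -0.52 and 0.41 over 15 pairs of a vehicle and a treated animal. With the animal number as a replicate block, 494, 2638, 286 and 2252 genes passed in the 4 strains, 2757 in the average effect, 2053 and 1828 in the contrasts, 3144 and 3585 in the vehicle levels and 2329 in the F test, and 18, 5 and 4 lists. Signal over background limits the dim genes most, and 5257 genes were set aside by the filter on the median. Without that filter 2754 genes passed in the average effect.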

Other observations

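Of 17 circadian clock genes 0 passed in MA/MyJ, where Nfil3 was at -0.73 and Nr1d1 at 0.62, and Clock passed as lower in each of the other strains. In NZW/LacJ the activator Arntl fell by 2.83 while Dbp (1.70), Per1 (1.62), Usp2 (1.18), Per3 (1.00) and Tef (0.64) rose and Cry1 (-1.0), Npas2 (-0.87) and Clock (-0.72) fell, so that 5 of 17 clock genes were higher and 4 lower (6 and 4 adjusted over the list alone). In WSB/EiJ 7 were higher, among them Nr1d1 (2.32), Dbp (1.58), Tef (1.21) and Cry2 (1.19), and Npas2 (-0.80) and Clock (-0.56) were lower (8 and 2 adjusted over the list alone, 8 and 2 without the array labelled WSB/EiJ PF-04287881 animal 3). In SM/J Cry1 (1.52) was higher and Nr1d1 (-1.43), Arntl (-1.08) and Clock (-0.55) lower. The list was not called in MA/MyJ (adjusted p = 0.379), NZW/LacJ (adjusted p = 0.970) or SM/J (adjusted p = 0.977). In WSB/EiJ it was called higher (adjusted p = 0.0335, and adjusted p = 0.504 with an estimated correlation), though not without that array (adjusted p = 0.0798). The effect on Arntl differed between NZW/LacJ and the other strains by -2.39 ± 0.34, and that on Cry1 between the vacuolation strains and the others by -1.40 ± 0.26. The labels give no time of day for dosing or killing.

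Of 24 cell cycle genes 7 rose in NZW/LacJ, and 4 rose and 1 fell in WSB/EiJ, in a list that the set test called in neither strain. In NZW/LacJ the cyclin Ccnd1 was at 2.66, the replication licensing factors Mcm6, Mcm2 and Mcm4 at 1.64, 1.58 and 0.97, the tubulin regulator Stmn1 at 1.11, Spc25 at 0.54 and Rrm1 at 0.44. In the necrosis contrast Ccnd1 (2.23), Mcm2 (1.55), Mcm4 (1.10) and Stmn1 (0.75) were higher and Rrm2 (-1.44) lower, again in a list not called.

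Some marker lists, picked after their scores were seen, ranked the treated NZW/LacJ animals alike. For Kupffer cell markers the scores of animals 1 to 4 were 0.67, 0.27, -0.28 and 1.13, for sinusoidal endothelial markers -0.05, -0.34, -0.69 and 0.29, and for stellate cell markers 0.23, -0.19, -0.45 and 0.53. Monocyte and lipid-associated macrophage markers had the same order, at 1.52, 0.59, 0.31 and 1.64. Other lists did not, with neutrophil markers at -0.12, 0.09, 0.06 and -0.02, T and NK cell markers at 0.03, -0.05, -0.02 and 0.25, B and plasma cell markers at 0.30, 0.19, 0.05 and 0.27, and cholangiocyte markers at 0.03, 0.14, -0.14 and 0.39.

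One strain's vehicle animals varied in interferon genes. The interferon response scores of WSB/EiJ vehicle animals 1 to 4 were -0.29, -0.53, -0.15 and 0.97, against 1.06, 0.86, 0.44 and 0.95 in the treated NZW/LacJ animals, each relative to the vehicle mean of its own strain.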
